A study of Homo sapiens with 6 samples.

How the data were processed

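RNA was sequenced from THP-1 cells, a human monocytic leukaemia line, after 6 h with 10 uM mebendazole or with the vehicle DMSO. Mebendazole is a benzimidazole drug against worms that binds beta tubulin. The 6 libraries form 3 pairs, with 3 libraries per group, and the labels give each sample's drug and pair. The labels do not say whether the pairs were separate cultures or days, so p-values measure the spread between these samples, which may be technical. That spread is largely pooled over genes, since a gene's own 2 residual degrees of freedom stood against a prior of 61. Very small p-values of single genes therefore rest mostly on the pooled spread, not on the gene's own replicates. Libraries were made from total RNA with an Illumina TruSeq RNA v2 kit, per the labels' protocols, a kit that selects poly(A) RNA and does not mark strand.

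The deposited table holds raw read counts per gene symbol, 1 column per sample, with no replicates pooled. STAR, bedtools, HTSeq and DESeq2 and the genome build hg19 are named, without versions or roles, per the submitters' processing notes. The gene annotation, the strand setting and any filter are not given in the sources used here. The table had 0 columns that belonged to no sample. No coordinates are printed, because the reference annotation used here is of another build. It served only for gene class, GC content and transcript length, by symbol. Of the 23710 symbols, 21257 matched by name, 1132 matched by an older or newer name and 1321 had no match.

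Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the group, which left 13591 genes with 99.9% of the reads, and 5164 genes had no read in any library. Libraries were scaled by TMM, and the quasi-likelihood F test (glmQLFit, glmQLFTest, two-sided) compared mebendazole with DMSO. The sample pair was a term of the model, because the labels state pairs. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM, reads scaled to a common library size with TMM factors, as mean ± SD of 3 libraries. The SE printed with a log2 fold change is the size of that change divided by the square root of its F statistic. It is not a standard error of the fit, and for large changes it can lie below counting error alone. All levels are relative to the RNA of the same library, so a change in total RNA per cell is not measured. Genes with 3 or fewer reads in one group are given as a ratio of summed counts with an exact 95% interval, which covers counting error only. Reads of near-identical genes (TUBA1A, TUBA1B and TUBA1C, the beta tubulin genes, HSPA1A and HSPA1B, CXCL1, CXCL2 and CXCL3, the histone genes) may be split between copies, and their single values are uncertain. Reads of overlapping and antisense genes cannot be told apart either.

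Before the data were examined, 31 gene lists, the test and the rule for named genes were fixed. The rule took the 12 largest rises and the 12 largest falls among called genes with a mean CPM of 10 or more and the same direction in all 3 pairs, the 4 members of each list with the smallest p, every tested alpha and beta tubulin gene, and a set of genes read as markers of monocyte and macrophage polarisation. Other members are named as examples of their list, chosen after their values were seen. Some genes that the rule or the lists take are not reported here. Lists with 5 or more tested members (30 lists) were compared with all other genes by camera (limma 3.58.1, preset inter-gene correlation 0.01, log CPM with prior count 2), adjusted over the lists. Calls within each list are given adjusted over all genes tested. Adjusted over the list alone, the counts were the same in every list except the cytosolic ribosomal proteins, where 25 genes in place of 24 were called higher. The lists covered alpha and beta tubulin, other microtubule genes, mitosis, DNA replication, p53 targets, immediate early genes, ERK feedback, inflammatory cytokines and NF-kB targets, M1 and M2 macrophage markers, Toll-like receptors and inflammasomes, aryl hydrocarbon receptor targets, SRF, MRTF and YAP targets, the integrated stress response, endoplasmic reticulum chaperones, heat shock, NRF2 targets, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis and MYC targets, monocyte and macrophage maturation, myeloid precursors, apoptosis regulators, lysosome and autophagy, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and markers of lymphocytes, of epithelial, stromal and endothelial cells and of erythroid cells and megakaryocytes. None of the mitochondrially encoded genes was in the table. Lists share members, so their calls are not independent. IL1B and TNF are in the cytokine and M1 lists, and IER3 is in the immediate early and ERK lists. SQSTM1 is in the NRF2 and lysosome lists. The apoptosis list shares BIRC3 with the cytokine list and TNFRSF10B with the p53 list.

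The test was run on simulated counts for mebendazole against DMSO with 200 changed genes, of which it recovered 66% at 1.25-fold, 90% at 1.5-fold, 94% at 2-fold and 100% at 4-fold over 13095 genes. Of the calls in that simulation, 3.33% were false. It used the dispersions estimated from these libraries, had no pair effect and left most genes unchanged. It therefore does not test the scaling, or whether the spread between these libraries is too low. Alternatives were no pair term, DESeq2 size factors, library totals, DESeq2 1.42.0, limma-voom, other filters, a GC offset, each pair left out, camera with an estimated correlation, and fry. Tests against a 1.5-fold change and with a set coefficient of variation of 0.1, and camera with DESeq2 size factors, were chosen after seeing the data.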

Results

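RNA levels were measured in THP-1 cells after 6 h with 10 uM mebendazole or with DMSO, in 3 libraries per group. Library totals ranged from 13420558 to 15727667 counts. Replicates of a group had Spearman correlations of at least 0.997, against 0.886 to 0.889 between groups, and no replicates agreed within sampling noise, so none was treated as a library deposited again. Of 13591 genes tested, 11192 were called changed, 5521 higher and 5671 lower with mebendazole.

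The comparison asked which genes differ between mebendazole and vehicle. THBS1, which encodes the matrix protein thrombospondin 1, rose from 3.03 ± 0.343 to 2158 ± 48.6 CPM (log2 fold change 9.48, SE 0.06, adjusted p = 3.7e-81, n = 3 per group, edgeR). Its ratio of summed counts was 714 (95% counting interval 606 to 848), an interval wider than that SE implies. STC1, the hormone stanniocalcin 1, had 2 reads in the DMSO libraries and 2892 with mebendazole, a ratio of 1704 (95% counting interval 471 to 14080). IL33, a cytokine, had 3 against 1093 reads, a ratio of 429 (147 to 2085). TFPI, an inhibitor of coagulation, rose by a log2 fold change of 9.29, KIAA1199 by 8.77, CRLF2, a cytokine receptor subunit, by 8.38, and ALDH1A2, an enzyme of retinoic acid synthesis, by 8.24. CCDC68 (7.98), HES4 (7.89), CCL20 (7.88), MAMLD1 (7.83) and TNFRSF18 (7.46) completed the 12 largest rises among genes with a mean CPM of 10 or more. Several rested on few DMSO reads, with 4 each for TFPI and CCDC68, 5 for HES4 and 7 for ALDH1A2. The ratio of summed counts of TFPI, 688, had a 95% counting interval of 268 to 2528, so the order of these rises is uncertain.

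Among the 12 largest falls of genes with a mean CPM of 10 or more, MNDA, a nuclear antigen of myeloid cells, fell from 129 ± 6.81 to 2.73 ± 0.232 CPM (log2 fold change -5.55, SE 0.08, adjusted p = 3.2e-58, n = 3 per group, edgeR). CCR2, the receptor that draws monocytes to CCL2, fell from 284 ± 0.887 to 13.2 ± 0.953 CPM (-4.43). CYBB, the catalytic subunit of the phagocyte oxidase, fell with a log2 fold change of -3.88. The others were EPHB1 (-5.54), NAV3 (-5.43), SERPINB2 (-5.41), NFE2 (-5.21), PHACTR3 (-4.78), TMEM229B (-4.73), CACNA2D3 (-4.63), FYB (-3.93) and PLAC8 (-3.71). At 2-fold or more, 2109 genes rose and 2017 fell, but with library totals 1704 rose and 2815 fell. With TMM, at 32-fold or more 139 rose and 12 fell, of which 61 and 5 had a mean CPM of 10 or more. Of the called genes, 11063 moved the same way in all 3 pairs.

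Inflammatory cytokines and NF-kB targets rose as a group. Of 30 tested, 29 rose and 1 fell, with a median log2 fold change of 3.44 (camera adjusted p = 4.5e-10; adjusted p = 0.311 with an estimated correlation). IL8, the neutrophil chemokine now named CXCL8, rose from 11.7 ± 1.74 to 1504 ± 90.1 CPM. IL1B rose from 8.20 ± 0.792 to 602 ± 59.5 CPM, and SOD2, a mitochondrial superoxide dismutase, rose 17.1-fold. The exception was TNF, at 145 ± 18.7 and 118 ± 5.54 CPM. The log2 fold change of TNF was -0.29 (adjusted p = 1.5e-07 in edgeR), lower in all but 1 of the 3 pairs, and DESeq2 did not call it (adjusted p = 0.113). IL6 had no read in any library, which limits it only to a level not detectable at this depth.

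Of 18 tested M1 markers, genes read as signs of pro-inflammatory macrophages, 13 rose and 4 fell (median log2 fold change 2.86, camera adjusted p = 0.0109; adjusted p = 0.367 with an estimated correlation, and adjusted p = 0.136 among genes with a mean CPM of 10 or more). SOCS3, a feedback inhibitor of cytokine signalling, rose 49.0-fold, and the costimulatory genes CD86, CD40 and CD80 rose 12.1-fold, 7.55-fold and 4.22-fold. IRF5, FCGR1A and TNF were among those that fell. M2 markers, read as signs of alternatively activated macrophages, went both ways, with 8 of 18 higher and 8 lower. Their median was -0.12 and their mean 1.09 (camera adjusted p = 0.751). CCL22, a chemokine for T cells, rose 140-fold to 1069 ± 39.6 CPM, and IRF4, TGM2 and IL1RN rose 33.8-fold, 20.9-fold and 4.92-fold. CLEC10A (-3.41), CCL13 (-3.10) and F13A1 (-1.91) fell. The log2 fold change of CD163 was -1.01 (adjusted p = 6.5e-04 in edgeR), with 98 reads in DMSO and 41 with mebendazole, and DESeq2 gave an adjusted p of 0.0549. MRC1 had no read in any library, and IL10 had 4 against 28 reads and was not tested.

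Toll-like receptor and inflammasome genes also went both ways, with 10 of 29 higher and 14 lower (camera adjusted p = 0.707). The receptor genes TLR5 (-2.09, SE 0.20), TLR7 (-2.01, SE 0.34), TLR2 (-1.26, SE 0.05), TLR8 (-1.24, SE 0.25) and TLR4 (-1.06) fell, and TLR9 (1.66), TLR1 (1.34) and TLR6 (0.77) rose. TLR7, TLR8 and TLR5 rested on 18, 48 and 55 reads with mebendazole. The inflammasome adaptor PYCARD fell from 94.2 ± 5.60 to 23.9 ± 3.00 CPM, and CASP1, the protease that matures IL-1 beta, from 69.6 ± 0.896 to 35.1 ± 0.462 CPM. IRAK2, a kinase downstream of Toll-like receptors, rose 33.0-fold. The log2 fold change of NLRP3, an inflammasome sensor, was 0.29 (adjusted p = 6.1e-10), but 0.05 (adjusted p = 0.253) with library totals. DYRK1B, a protein kinase, fell from 3.32 ± 0.324 to 1.84 ± 0.222 CPM.

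**Figure D1:**
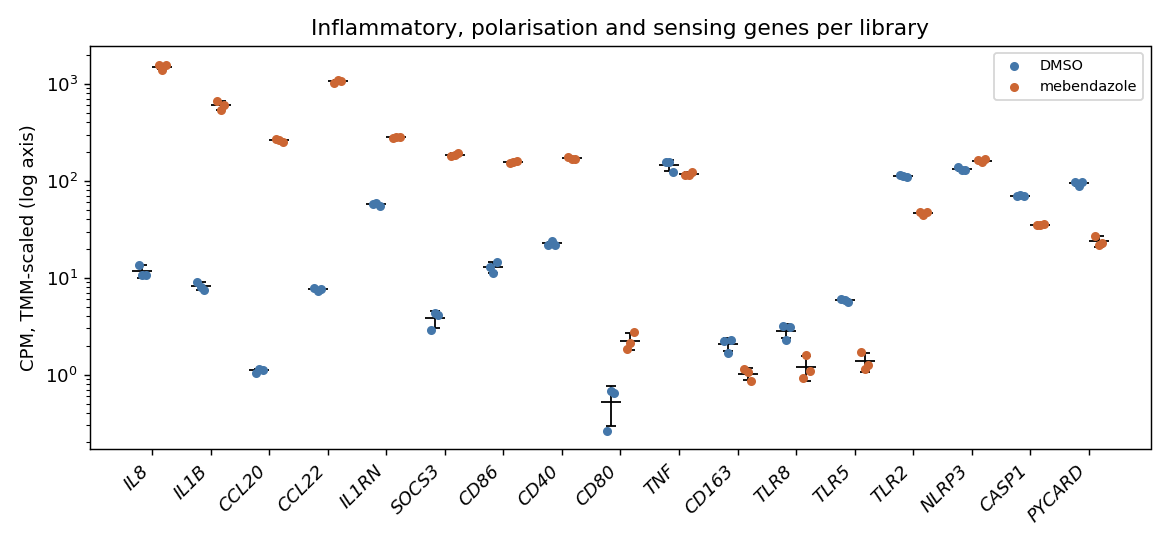
CPM (TMM-scaled, log axis) of inflammatory, polarisation and sensing genes in each library, with 3 DMSO points (blue) and 3 mebendazole points (orange) per gene; black bars are mean ± SD. IL8 stood at 1504 CPM with mebendazole against 11.7 in DMSO, and PYCARD at 23.9 against 94.2.

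Tubulin genes, which encode the protein that mebendazole binds, split by gene. Of 11 tested, 5 rose and 5 fell, and with library totals 4 rose and 6 fell (camera adjusted p = 0.752). The abundant TUBA1B fell from 579 ± 17.1 to 147 ± 2.87 CPM (log2 fold change -1.98, SE 0.03) and TUBB from 408 ± 9.22 to 115 ± 3.64 CPM (-1.83, SE 0.04). TUBB4B (-0.85), TUBA1A (-0.64) and TUBA1C (-0.36) also fell. TUBA4A rose from 27.0 ± 1.46 to 125 ± 0.142 CPM (2.21, SE 0.05), and TUBB2A (2.52), TUBB3 (1.68) and TUBA8 (0.68), each under 6 CPM, rose too. TUBB6 was called higher at 0.21 but lay at -0.03 with library totals. TUBB1, at 2.09 ± 0.432 and 1.71 ± 0.445 CPM, did not pass the test. With library totals it did, as the log2 fold change of TUBB1 was then -0.53 (adjusted p = 0.0367). Other microtubule genes went both ways, with 11 of 25 higher and 11 lower (camera adjusted p = 0.827). MAPRE2, CLASP1, DYNC1H1 and TUBGCP2 rose, and TBCD, a tubulin folding cofactor, fell.

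**Figure D2:**
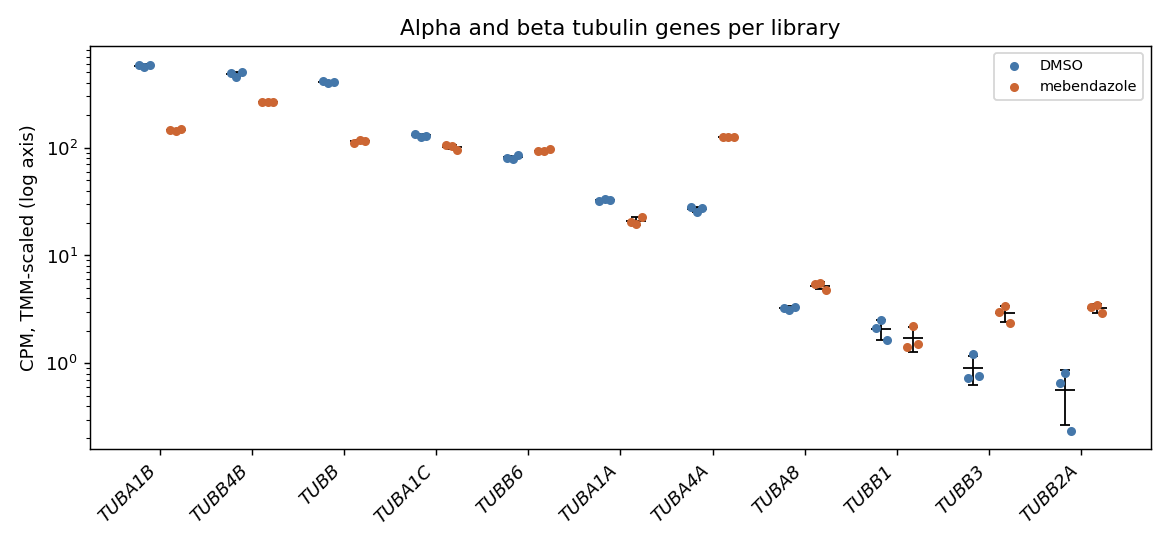
CPM (TMM-scaled, log axis) of the 11 tested alpha and beta tubulin genes in each library, with 3 DMSO points (blue) and 3 mebendazole points (orange) per gene; black bars are mean ± SD. TUBA1B and TUBB lay lower with mebendazole and TUBA4A higher, and TUBB6, slightly higher here, was at -0.03 (log2) with library totals.

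Cell cycle genes were lower. Of 30 mitosis genes, 26 fell and 1 rose (median log2 fold change -0.48, camera adjusted p = 5.8e-04; adjusted p = 0.367 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 380 ± 22.2 to 198 ± 1.56 CPM, and CCNB1, HMMR and TOP2A fell by log2 values of -1.13, -1.24 and -0.63. Of 28 DNA replication genes, 17 fell and 4 rose (median -0.22, camera adjusted p = 0.0317; adjusted p = 0.365 with an estimated correlation, and adjusted p = 0.0598 without pair 2). MCM2 and MCM3 of the replicative helicase fell by -1.20 and -1.11, and UNG, a uracil-DNA glycosylase, by -1.47. Of 20 p53 targets, 16 rose and 3 fell (median 1.12, camera adjusted p = 8.7e-04; adjusted p = 0.311 with an estimated correlation). The cell cycle inhibitor CDKN1A rose by 3.70 on the log2 scale, the death receptor gene TNFRSF10B 9.86-fold, BTG2 8.41-fold and PLK3 5.01-fold. FDXR fell (-2.07). These cells are reported to lack functional p53, and BTG2 is also in the immediate early list, so the rises are not read as p53 activity.

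Of 28 immediate early genes, 23 rose and 2 fell (median log2 fold change 1.97, camera adjusted p = 3.1e-06; adjusted p = 0.311 with an estimated correlation). The nuclear receptors NR4A2 and NR4A1 rose 134-fold and 38.2-fold and FOSL2 15.8-fold, whereas EGR1 (-1.35) and MYC (-0.80) fell. ERK feedback genes were higher in 11 of 16 and lower in 3 (median 1.79, camera adjusted p = 0.00868; adjusted p = 0.368 with an estimated correlation). The phosphatase gene DUSP4 rose from 15.1 ± 0.195 to 1121 ± 21.8 CPM, PHLDA1 rose 43.8-fold, IER3 36.3-fold and DUSP6 3.65-fold, and SPRY4 (-1.10) and ETV4 (-1.35) fell. SRF, MRTF and YAP targets, genes of the actin cytoskeleton and matrix, rose in 18 of 24 and fell in 5 (median 0.95, camera adjusted p = 0.00522; adjusted p = 0.311 with an estimated correlation, and adjusted p = 0.0793 among genes with a mean CPM of 10 or more). TPM4, a tropomyosin, rose 6.37-fold and MYH9, a non-muscle myosin, 2.18-fold. NRF2 targets of the oxidative stress response rose in 15 of 20 and fell in 4 (median 1.21, camera adjusted p = 0.00243; adjusted p = 0.311 with an estimated correlation). The ferritin gene FTH1 rose from 704 ± 24.2 to 5084 ± 180 CPM, and SQSTM1 and HMOX1 rose 6.28-fold and 5.22-fold. Lysosome and autophagy genes rose in 23 of 27 and fell in 2 (median 0.66, camera adjusted p = 7.7e-05; adjusted p = 0.311 with an estimated correlation), among them MAP1LC3B (3.42-fold) and GLA (2.78-fold). Apoptosis regulators rose in 18 of 25 and fell in 4 (median 0.92, camera adjusted p = 0.00138; adjusted p = 0.311 with an estimated correlation). The members with the smallest p included the inhibitors of cell death BIRC3 (24.4-fold), CFLAR (5.50-fold) and MCL1 (5.01-fold), and the promoters PMAIP1 (1.14) and BBC3 (1.47) rose on the log2 scale too.

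Ribosome biogenesis genes and heat shock genes fell. Of 28 ribosome biogenesis genes and MYC targets, 27 fell and 1 rose (median log2 fold change -1.04, camera adjusted p = 2.7e-07; adjusted p = 0.311 with an estimated correlation). ODC1 and SRM, enzymes of polyamine synthesis, fell by -2.50 and -1.94, and CAD, which starts pyrimidine synthesis, by -1.52. Of 18 heat shock genes, 16 fell and 2 rose (median -0.87, camera adjusted p = 7.4e-04; adjusted p = 0.311 with an estimated correlation). The chaperone HSPA8 fell from 4860 ± 76.6 to 2012 ± 75.6 CPM, and HSPB1 (-1.98) and FKBP4 (-1.61) fell, while HSPA6 (1.26) and BAG3 (0.59) rose. Cytosolic ribosomal protein genes moved little, with 24 of 30 called higher (median 0.17, camera adjusted p = 0.00868; adjusted p = 0.610 with an estimated correlation), but with library totals 7 were higher and 16 lower and the list was not called (adjusted p = 0.891), nor was it among genes with a mean CPM of 10 or more (adjusted p = 0.0574).

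Several metabolic and stress lists did not pass the list test. Most of their members were called, but so were 82.3% of all genes tested. Endoplasmic reticulum chaperone genes were lower in 12 of 19 and higher in 5 (camera adjusted p = 0.0799), with PDIA4 at -1.63, CALR at -1.07 and EDEM1 at 1.08. Integrated stress response genes were higher in 14 of 23 and lower in 7 (adjusted p = 0.105, but called higher with library totals, adjusted p = 0.0487). VEGFA, the angiogenic growth factor, rose 10.9-fold to 1822 ± 66.1 CPM and SLC7A11 7.76-fold, and the serine synthesis genes PSAT1 (-2.49) and PHGDH (-1.52) fell. Glycolysis and hypoxia genes were higher in 15 of 27 and lower in 10 (adjusted p = 0.105), with the transporters SLC2A1 and SLC16A3 up 3.15-fold and 3.17-fold. Cholesterol synthesis genes were lower in 14 of 22 and higher in 4 (adjusted p = 0.0950), with FDFT1 at -1.30 and SQLE and INSIG1 at 1.49 and 1.58. Interferon-stimulated genes were lower in 13 of 28 and higher in 8 (adjusted p = 0.425), with ISG20 at 4.97 and IFI35 at -2.22. Aryl hydrocarbon receptor targets were higher in 5 of 8 and lower in 3 (adjusted p = 0.523). The receptor gene AHR itself rose 5.46-fold, the targets AHRR (-1.36) and CYP1B1 (-1.04) fell, and CYP1A1, with 8 reads in DMSO and 25 with mebendazole, was not tested.

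Replication-dependent histone genes rose in 8 of 9 tested, with none lower (median log2 fold change 3.00, camera adjusted p = 0.00522; adjusted p = 0.311 with an estimated correlation). HIST2H2BE rose from 9.61 ± 0.653 to 50.9 ± 1.2 CPM and HIST1H2BD 11.1-fold. Their mRNAs mostly lack a poly(A) tail, and DMSO replicate 1 held more reads of the RNAs RMRP (105) and RPPH1 (126), which lack one too, than the other libraries (1 to 5 each). Maturation genes of monocytes and macrophages went both ways, with 9 of 28 higher and 16 lower (camera adjusted p = 0.270). The protease genes CTSL1 and CTSB and the integrin gene ITGAX rose 8.29-fold, 3.02-fold and 7.16-fold, and S100A8 (-3.09), S100A9 (-2.55) and CD14 (-1.06) fell. Myeloid precursor genes were lower in 10 of 20 and higher in 7 (adjusted p = 0.425), with the transcription factors MYB and GFI1 at -3.27 and -2.75 and RUNX1 and SPI1 at 1.18 and 0.98. Among markers of other cell types, 5 of 6 lymphocyte genes rose and 1 fell (adjusted p = 0.0690; adjusted p = 0.0185 with library totals and 0.0427 without pair 3). IL7R, a cytokine receptor, rose from 7.23 ± 1.23 to 1009 ± 14.5 CPM, while the T cell genes CD3D, CD3E and CD3G had 5, 1 and 2 reads in DMSO and 0 with mebendazole. Epithelial, stromal and endothelial markers were higher in 2 of 5 and lower in 1 (adjusted p = 0.472), and erythroid and megakaryocyte markers lower in 3 of 5 with none higher (adjusted p = 0.407).

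**Figure D3:**
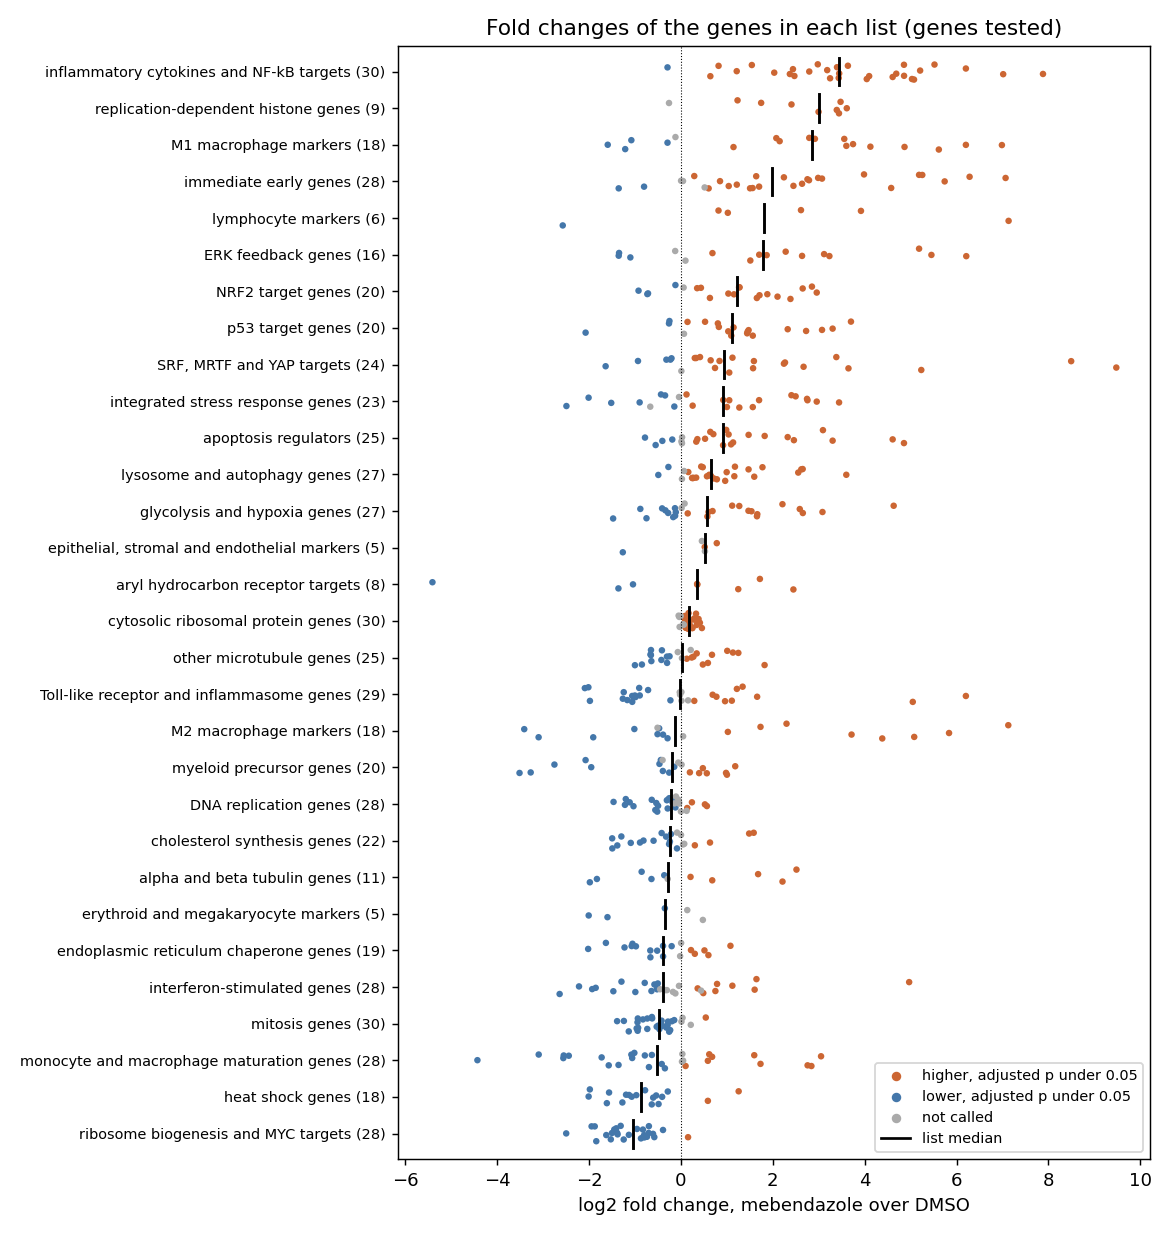
Log2 fold change of each tested gene, mebendazole over DMSO, for 30 gene lists ordered by their median (black bar); orange points were called higher, blue lower and grey were not called. The cytokine list had the highest median (3.44) and ribosome biogenesis the lowest (-1.04), and the ribosomal protein genes, higher here, were mostly lower with library totals.

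The gene calls rest on edgeR's quasi-likelihood test with 3 libraries per group, and the list calls on a preset correlation, since with an estimated correlation 0 of 30 lists passed while fry called 28. With library totals the median log2 fold change shifted by -0.24, and 36.4% of the called genes were higher against 49.3% with TMM, so the balance of rises and falls, at 2-fold or more too, and the direction of small changes hold only relative to the chosen scaling.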

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

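Of 148 named genes, 138 had the same sign and call in every alternative that tested them. Counts of changed genes (11192) and of genes changed at least 2-fold (4126) stayed within 1.5 times in all but these alternatives: 5774 genes passed a test against a 1.5-fold change, chosen after seeing the data, which asks for a larger change, and 2308 genes changed at least 2-fold among those with a mean CPM of 10 or more, where fewer genes were tested (9501). For lists, 15 of 30 were called, 0 with an estimated correlation and 28 with fry, which does not compare a list with other genes. With 2 residual degrees of freedom, camera with the estimated correlation also missed 30 simulated genes raised together by 1.5-fold (adjusted p = 0.0879). That simulation drew genes independently and left all others unchanged, unlike these data, so it does not show why 0 lists passed. TUBB6 reversed with library totals (-0.034 against 0.21), by the shift of -0.24 that this scaling gives the median gene; 190 called genes were called the opposite way. Without 1 pair, 10572 to 10885 genes changed, 4182 to 4242 at least 2-fold, and 14 to 16 lists were called. EPOR lost its call without any 1 of the pairs, KRT8 without pair 3, and COL1A1 gained one without pair 1; the cause was not tested. With no replicate block, 11118 genes, 4130 at least 2-fold and 15 lists were called, and no named gene changed its call. Deviations of samples with the same pair number correlated at -0.01, 0.13 and 0.06, and not every sample correlated best with its own number. Other pseudocounts were not run, because the table holds counts. Genes with few reads, such as TLR8 and CD163, are limited by depth.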

Other observations

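The scan of gene families by symbol, the tests of scaling, tubulin and histones, and the count of other splits were chosen only after the results were seen. A scan of all 202 families of protein-coding genes that share a symbol stem and had 8 or more tested members called 16 (camera, adjusted over the 202 families), 6 higher and 10 lower, and 0 with an estimated correlation, where these families had an adjusted p of 0.809. Mitochondrial ribosomal proteins of the large subunit (MRPL) fell in 37 of 47 and rose in 2 (median log2 fold change -0.44, adjusted p = 0.00103), and those of the small subunit (MRPS) fell in 24 of 29 and rose in 2 (-0.66, adjusted p = 0.00365). The 8 tested genes with the stem CCT, which name subunits of a chaperonin that folds actin and tubulin, fell (-0.73, adjusted p = 0.0271), as did 14 of 16 aldehyde dehydrogenases (ALDH, -1.17, adjusted p = 0.0271) against the rise of ALDH1A2. TNF receptor family genes (TNFRSF) rose in 11 of 14 and fell in 2 (1.61, adjusted p = 0.0271). The SIGLEC genes, 10 of 11 lower, did not pass (adjusted p = 0.0883).

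Single genes outside the lists, chosen after their values were seen, also moved far. CXCR4, a chemokine receptor, rose 5.18-fold to 461 ± 4.97 CPM, and CXCR2, the receptor of IL8, fell from 13.2 ± 0.935 to 1.33 ± 0.195 CPM. The immunoproteasome genes PSMB8 and PSMB9 fell by log2 fold changes of -2.63 and -2.74. MT2A, a metallothionein, rose 20.9-fold and KDM6B, a histone demethylase, 12.8-fold. IGFBP5 rose 91.3-fold.

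Most genes tested were called changed. With a coefficient of variation of 0.1 set for every gene, in place of the 0.0273 estimated, 70.9% were still called, but that value was assumed, and no spread between separate cultures was measured, so a low spread between these replicates cannot be excluded as a cause. Library totals called 84.6%, but this count cannot test scaling, since a shift of all genes would itself add calls. Changes of 2-fold or more went both ways under each scaling (2109 higher and 2017 lower with TMM, 1704 and 2815 with library totals). A scaling error moves all genes of a library the same way, which argues against scaling as the whole cause of these larger changes. For smaller changes the counts do not decide. A GC offset per library gave 100.3% of the count without it, which argues against GC content as the whole cause. The 6 libraries make only 10 splits, too few for a share under 0.05; 1 split, the real one, gave 11118 genes without the pair term, and the highest other 0. A broad response to the drug and a low spread between these replicates both stay open.

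TUBA1B and TUBB fell while other tubulin genes rose. With library totals their mean log2 fold change was -2.15, and summed alpha and beta tubulin CPM were lower in every mebendazole library (log2 ratios -0.95 and -1.01; exact permutation p = 0.1, the smallest that 3 against 3 allow), which argues against scaling and against reads moving between paralogs. Of 58 mitosis and DNA replication genes, 0% fell as much as TUBB (lowest UNG, -1.47), so fewer dividing cells would not account for the fall. The levels of all tubulin mRNAs did not fall together, since 4 genes were higher under 3 scalings. Of these, TUBA4A rose from 27.0 ± 1.46 to 125 ± 0.142 CPM, and the others had few reads. Whether decay was shared by all tubulin mRNAs was not measured, so levels alone do not exclude it. Decay of the mRNAs of abundant tubulins when free tubulin rises may be the biological cause, as a hypothesis with no measure of decay here.

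Summed histone reads were 4.24 times as high with mebendazole. A first test of whether the mebendazole libraries held more RNA without a poly(A) tail had only 1 tested gene and was replaced, after the reads were seen, by the sum over 18 such RNAs with a bound of 2-fold, leaving out DMSO replicate 1 for its RMRP and RPPH1 reads. That sum was 1.23 times the level of DMSO replicates 2 and 3 (95% counting interval 0.920 to 1.65), which argues against carry-over of these 18 RNAs of 2-fold or more. It was 0.398 times that of all DMSO libraries, but DMSO replicate 1 held 282 such reads against 43 and 36 in replicates 2 and 3. That ratio therefore adds no support. More cells in S phase is argued against by the DNA replication genes, whose median log2 fold change was -0.22. Polyadenylated histone transcripts may account for the rise, a hypothesis that counts per gene cannot test.

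CCR7, CCL22 and CD86 rose, which raised the hypothesis of a gene programme of dendritic cell maturation. A list of such genes not yet looked at, of which 14 were tested, had a median log2 fold change of 0.97, at the 99.6th percentile of 10000 random lists matched on mean CPM, with 8 higher and 2 lower. CD83 rose 12.2-fold and IL4I1 3.54-fold, but FSCN1, an actin bundler of mature dendritic cells, fell (-0.26), and CD274 and PDCD1LG2 did not pass the test (-0.64 and -0.41). The NR4A genes likewise raised the hypothesis of cyclic AMP signalling through CREB. Of 12 tested CREB targets not yet looked at, 10 rose and 1, CITED2, fell (-1.19), and their median of 3.17 lay above all 10000 random lists (percentile 100). PDE4B and DUSP1 rose 19.7-fold and 24.5-fold. Both results are what these programmes would give, but several members are also NF-kB or immediate early targets, and the tests do not tell these apart. The random lists were matched on mean CPM alone and do not allow for genes that move together. Neither camera nor fry was run on these lists, so the percentiles give only their rank among random lists.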
